A study of Rattus norvegicus with 6 samples.

How the data were processed

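Gene expression was measured in the nucleus accumbens of 6 rats with Affymetrix Rat Gene 2.0 ST arrays, 1 array per rat, a platform whose probes are summarised into transcript clusters. Per the labels, 3 rats were infused on both sides with 2.0 µl of a lentivirus carrying GFP (LV-GFP, 8.28e+08 infectious units per mL) and 3 with 2.0 µl of a lentivirus that overexpresses the microRNA miR-495 (LV-miR-495, 1.39e+09 per mL). The tissue was taken 1 week later, both accumbens of an animal were pooled, and total RNA was extracted with Trizol. The samples are labelled as biological replicates, so the spread between arrays includes the spread between animals.

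The deposited values came in 3 tables. The first table holds 29573 transcript clusters without gene names, as linear intensity values that the authors deposited under a heading calling them raw. Its 6 columns carry rat numbers, and per the file headers rats 1, 3 and 9 are controls and rats 6, 8 and 10 received miR-495. The series' design text also names rats 1, 3 and 9 as the LV-GFP animals. The array medians of this table lay between 172.9 and 181.6. The file header names annotation release na33 and genome build rn4. A further 6 columns of that table, headed normalized, were not used. The second table holds log2 expression values for 20334 gene identifiers, deposited by the authors to 2 decimals, with array medians from 7.80 to 7.88 and columns named by sample accession. The third is the authors' deposited comparison table of 1027 rows with a gene symbol, the mean intensity of each group, its SD, the ratio of the means (LV-miR-495 over LV-GFP) and a t-value used as a score. MAS5 and RMA are named in the submitters' processing notes, without versions and without saying which table each made. The intensity table carries MAS5 in its deposited name, although its heading calls the values raw. Beyond that name, the normalization method of each table is not given in the sources used here.

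Gene identifiers of the second table were named through an NCBI RefSeq gene table of assembly GRCr8, where 19506 of the 20334 (95.9%) were found. The other 828 were left out. That assembly differs from the array's build, so no coordinates are given. The transcript clusters were left unnamed except for the authors' 1027 rows, each of which matched exactly 1 cluster, because their group means equal the means of 2 arrays per group to within a relative tolerance of 2e-06.

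The sample labels of the log2 table did not match the rat names of the intensity table, and this affects every direction given for a named gene. The match used 928 genes of the authors' comparison table that were found in both tables. Each gene's deviations from its mean over the 6 arrays were correlated between every column of one table and every array of the other. Each log2 column matched 1 rat and no other, and 4 of the 6 columns matched a rat of the opposite group. The rat-named table is therefore used with its own groups for all counts of transcript clusters. The log2 table was analysed with both groupings, once as its accession labels state and once with each column in the group of the rat it matched. This second grouping takes a column's group from the values of its array and not from its sample label, and it was chosen after the data were examined. It is the grouping behind the named genes and gene lists below unless accession labels are mentioned, and the value under the accession labels is given beside the main results. Which of the labels is wrong was not settled by any source used here.

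Intensities were analysed as log2(value + 1), log2 values as deposited. The 30% of features with the lowest mean over all 6 arrays were left out, which kept 20701 transcript clusters and 13652 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The plan made before the data were examined called for a gene-level test on the larger table. That table carries no gene names, so its test was run on transcript clusters instead. For 24 gene lists fixed before the data were examined, camera was run with a preset inter-gene correlation of 0.01 and again with an estimated one, with fry beside it, all two-sided and adjusted over the 24 lists. These adjusted p-values are limma's. Members of each list were also counted with p adjusted over the list alone. Exact permutation tests of 3 rats against 3 cannot go below p = 0.1 (two-sided).

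Named genes follow a rule set in advance. It takes the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap. A direction with fewer is filled in the order of limma's unadjusted p, and these are stated to be short of the threshold. Bdnf, Camk2a, Arc and Mir495 are always named, as are up to 4 members of a described list with the smallest p. The rule was applied to the log2 table, and called transcript clusters that carry a symbol are named besides. Some results that the rule would name are not reported here.

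The pipeline was tested on simulated data with these arrays' means and spread. With a log2 change of 0.5, 1 or 2, 25.7%, 65.3% and 87.3% of changed transcript clusters were recovered among 20701, and 24.6%, 73.8% and 95.5% of changed genes among 13652. Of 200 simulated lists without a shift among 13652 genes, 4 had a camera p under 0.05. The simulated noise was independent between genes, so this does not measure false calls in lists of correlated genes. In the real data the estimated inter-gene correlation was 0.69 for medium spiny neuron genes and 0.88 for interferon genes. Arrays give no read depth, and their number, 3 per group, limits the precision.

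Alternatives were quantile normalization and median centring of the arrays, other filters on dim features, a pseudocount of 16, a trended and robust prior, array weights, leaving out each rat, an adjusted p of 0.1 and the other table or grouping. Leaving out rats 8 and 9 together was added after the data were examined. The accession labels give both groups replicate numbers 1, 2 and 3. Under those labels the deviations of same-numbered columns from their group means correlated at r = 0.78, 0.37 and 0.51 across genes. By the array match, number 1 joins rats 10 and 6, both named LV-miR-495, and number 3 joins rats 3 and 1, both LV-GFP. For these numbers the correlation therefore does not show a pairing by number. The correlations led to a fit with the number as a block, which passed 0 genes, as did the fit without it. With 10 lists past the threshold against 5 at the preset correlation, the block did change the list tests, while 0 passed with an estimated one in either fit. Combining the estimated correlation with the accession labels, a block, a left-out rat or no filter was added after the data were examined, as was leaving out each rat for Mir495. The rat-named columns carry no such number of their own, and a block with the numbers passed on by the array match was added after the data were examined. A planned test of genes with miR-495 seed sites in their 3' untranslated regions was not run, because no transcript sequences were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.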

Results

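The series measured gene expression in the nucleus accumbens, a striatal region of the reward circuit, 1 week after infusion of a lentivirus. LV-miR-495, which overexpresses the microRNA miR-495, was given to 3 rats, and 3 received LV-GFP, the control virus. The comparison asks which transcripts differ in the accumbens when miR-495 is overexpressed, and the study's known interest is in Bdnf, Camk2a and Arc as targets of this microRNA. Arrays correlated with each other at r = 0.962 to 0.992 across transcript clusters.

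The labels of the deposited tables conflict. Columns of the gene table were matched to the rat-named arrays over 928 genes, and each column had an r of 0.931 to 0.974 with 1 array, while no other pairing exceeded 0.410. The columns labelled LV-GFP replicates 1 and 2 matched rats 10 and 8, which are named as LV-miR-495 rats, and replicate 3 matched rat 3. The columns labelled LV-miR-495 replicates 2 and 3 matched rats 9 and 1, which are named as LV-GFP rats, and replicate 1 matched rat 6. Directions for named genes below hold for columns placed by matched rat. Most turn around under the accession labels, largely because these move 4 of the 6 columns to the opposite group.

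**Figure D1:**
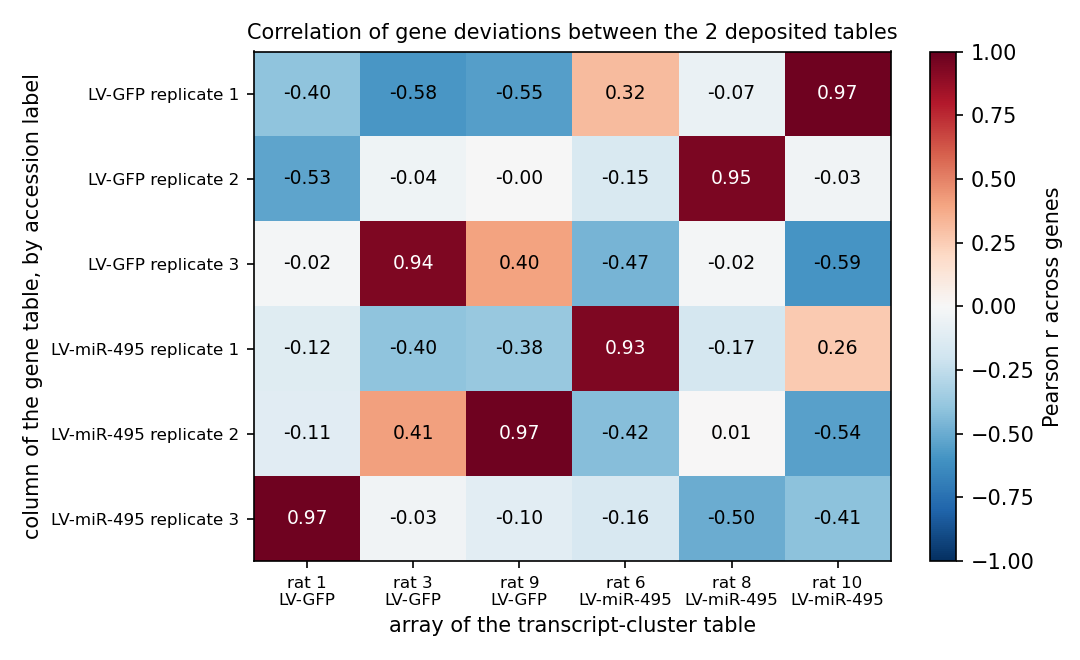
Pearson correlation across 928 genes between each column of the gene table (vertical axis, by accession label) and each rat-named array of the transcript-cluster table (horizontal axis), after removing each gene's mean. Each column has 1 array at r of 0.931 or more, and 4 of these 6 lie in the opposite group.

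The overexpressed microRNA was examined first as a check of the labels. The Mir495 probe set, which reads the precursor transcript, gave log2 values of 5.09, 5.06 and 5.88 in rats 6, 8 and 10 and 4.62, 5.01 and 4.58 in rats 1, 3 and 9. The difference was 0.61 (SE 0.24), with an exact two-sided permutation p of 0.1, the smallest 3 against 3 allows, and a limma adjusted p of 0.217. Without rat 10 it was 0.34, and 0.53 to 0.75 with any other rat left out. Under the accession labels the difference was -0.55. Mir411, another microRNA of the cluster, differed by 0.60 (SE 0.14, adjusted p = 0.124), also without overlap of the groups. Of 23 cluster transcripts ranked by rise, Mir495 was number 2, and the groups overlapped for 15. The other 8 were 6 higher and 2 lower, and over all 13652 genes tested the groups did not overlap for 28.9%. The Mir495 and Mir411 probe sets were dim, at percentile 8.16 of mean expression for Mir495 and 5.27 for Mir411. Mature miR-495 is not measured by the Mir495 probe set.

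Across transcript clusters grouped by rat name, 45 of 20701 were higher and 20 lower in LV-miR-495 rats at a limma adjusted p under 0.05. At an unadjusted p under 0.05 the numbers were 2154 and 2435. The 2 groups did not overlap for 5996 clusters (29.0%), against 10% by chance. Of the 65 clusters past the threshold, 7 carry a symbol in the authors' deposited table, which lists falling clusters only. Among them the transcription factor Tshz3 fell by 1.44 on the log2 scale (SE 0.17). Serinc2 fell by 1.23, Cnih3 (an AMPA receptor auxiliary subunit) by 1.06, Mal2 by 0.99, Kcnv1 (a potassium channel subunit) by 0.95 and Or7e24 by 0.91. No cluster passed when rat 1, 3, 6 or 10 was left out, while 1286 were higher and 876 lower without rat 8, and 34 and 12 without rat 9. A fit blocked on the replicate numbers passed on by the array match left 0 clusters, and it compares rats 8 and 9 alone.

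In the gene table with columns placed by matched rat, 13 of 13652 genes rose and 2 fell. Gpr149, an orphan receptor, rose by 2.21 (log2, SE 0.19), from 6.45 ± 0.36 (SD, n = 3) in LV-GFP rats to 8.65 ± 0.19 (n = 3). The serotonin receptor Htr4 rose by 1.84, the transcription factor Foxp2 by 1.80 and the retinoid receptor Rxrg by 1.64. Dlk1 rose by 1.55, the striatal phosphodiesterase Pde10a by 1.48, Sh3rf2 by 1.48, Foxo1 by 1.17, Adamts6 by 1.02, Kctd8 by 0.95 and Gpr101 by 0.91. Their adjusted p lay between 0.0425 and 0.0437. Tshz3 fell by 1.59 (SE 0.17) and Tmem178a by 1.23 (SE 0.13). The fit does not account for differences in the make-up of the dissected tissue, which are considered below. No gene passed in either direction when rat 1, 3, 6 or 10 was left out or when dim genes were kept, while 1067 were higher and 709 lower without rat 8, and 34 were higher without rat 9. The block on replicate numbers, which rests on rats 8 and 9, left 0 genes. With the accession labels, 0 genes passed limma's adjusted threshold, and each of these 13 named genes had the opposite sign. These labels move 4 of the 6 columns to the opposite group, so a difference by matched rat turns around and shrinks largely by arithmetic. Each group then mixes both kinds of rat, which widens its spread for such genes. The opposite signs are thus no separate result. At an unadjusted limma p under 0.05, 101 were higher and 72 lower under these labels, against 1669 and 1571 by matched rat. The total of 173 among 13652 is below the share of 0.05 that no group difference gives on average.

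The falling side was filled by unadjusted p with 10 genes short of the threshold. Serinc2 had a log2 fold change of -1.34 (SE 0.19, adjusted p = 0.0516), Adra1d (an adrenergic receptor) -1.14, Cpne4 -1.11 and Mal2 -1.04. The values were -0.99 for Kcnv1, -0.95 for Or7e24, -0.87 for Gng2, -0.69 for Tmem108 and -0.63 for the pseudogene Gbp6-ps1. In all 10 the 3 LV-miR-495 rats lay below the 3 LV-GFP rats, and the signs turned with the accession labels. Over the 928 genes matched between the tables, log2 fold changes of the 2 tables correlated at r = 0.954 across genes, and 924 had the same sign. These genes are not independent replicates. They come from the authors' table of falling clusters, and the columns were placed by matching these same genes. The agreement was thus largely fixed beforehand and is no independent check.

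Of the reported miR-495 targets, Bdnf (a neurotrophin) and Arc (an activity-regulated synaptic protein) fell with p adjusted over the list alone, and none of the 3 passed over all genes tested. The study chose these genes, so the first count is not independent evidence. Bdnf had a log2 fold change of -0.88 (SE 0.13, adjusted p = 0.0529) and Arc -0.82 (SE 0.16, adjusted p = 0.0871), and in both every LV-miR-495 rat was below every LV-GFP rat. Camk2a, a synaptic kinase, had -0.19 (SE 0.12, adjusted p = 0.382), with overlapping groups. The matching transcript clusters gave -0.57 for Bdnf, -0.76 for Arc and -0.28 for Camk2a. As a list they were lower (median -0.82, camera adjusted p = 0.00412, adjusted p = 0.279 with an estimated correlation). Their median was 0.18 with the accession labels. Cortical excitatory neuron markers, a list that includes Bdnf and Camk2a, fell in the same rats (median -1.19, 13 of 15 adjusted over the list alone). The authors' deposited table gives ratios of 0.651 for Bdnf, 0.567 for Arc and 0.746 for Camk2a.

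**Figure D2:**
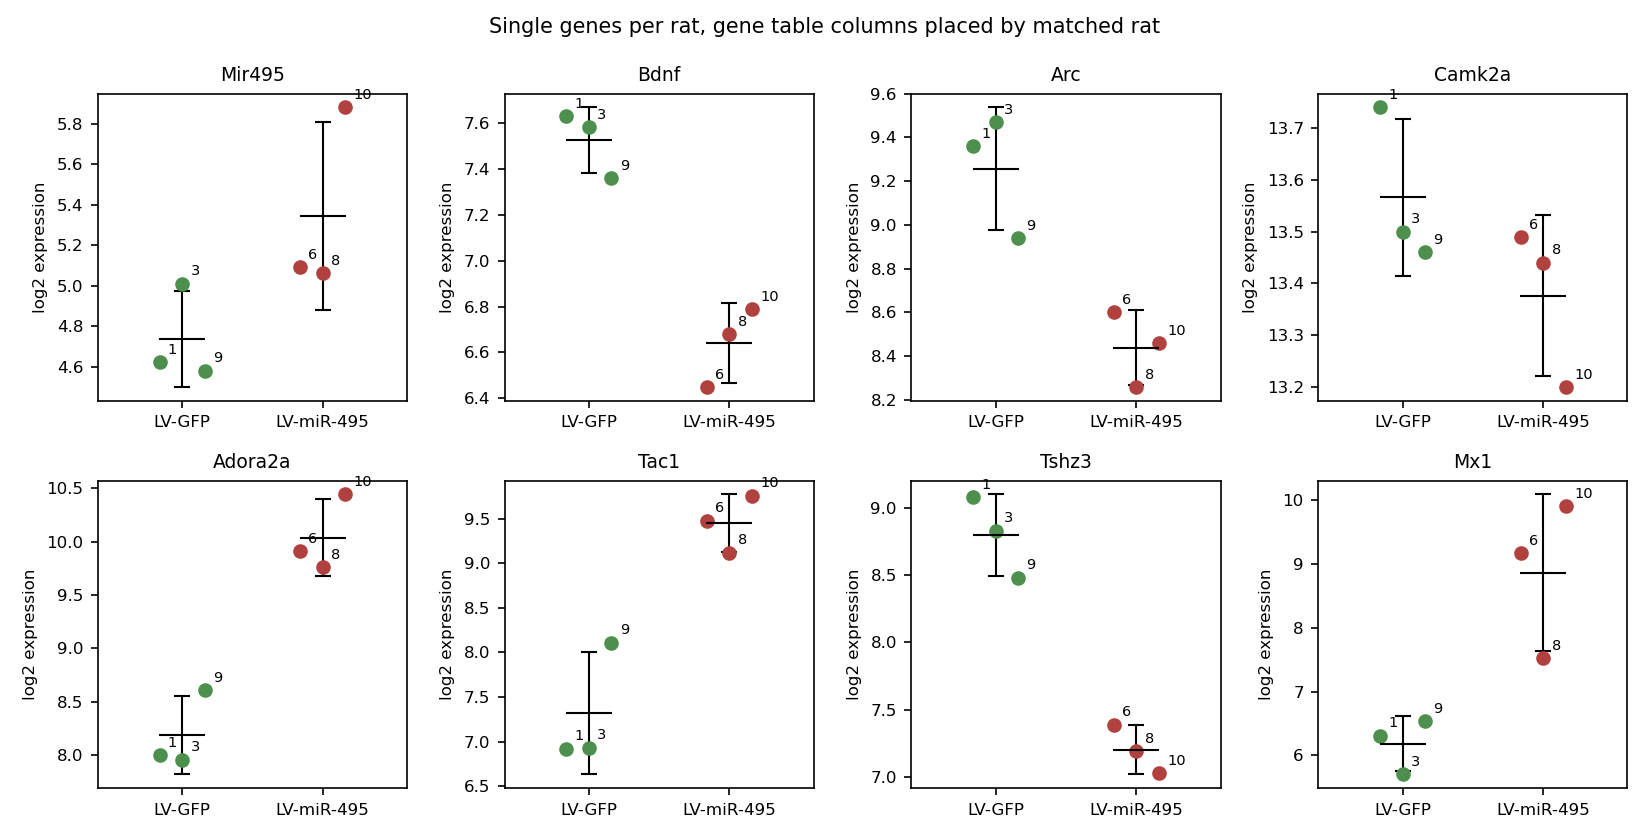
Log2 expression (vertical axes, a separate range per gene) of 8 genes in each rat, with gene table columns placed by matched rat. Points are rats with their numbers, and bars are the group mean ± SD (n = 3). Bdnf, Arc, Adora2a, Tac1, Tshz3 and Mx1 show no overlap of groups, and Camk2a overlaps.

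Markers of medium spiny neurons, the principal cells of the accumbens, rose as a group. Of 29 measured, 27 rose with p adjusted over the list alone, 2 of them over all genes tested, including Pde10a, and the median log2 fold change was 1.27. The adenosine receptor Adora2a rose by 1.85 (SE 0.24) and the striatal phosphatase Ptpn5 by 1.20 (SE 0.17) adjusted over the list alone. The camera adjusted p was 9.99e-20, and it was 0.305 (adjusted p) with an estimated correlation. Direct pathway genes had 6 of 8 rises adjusted over the list alone and 0 over all genes (median 0.70), with Tac1, the substance P precursor, at 2.13 and Pdyn, the dynorphin precursor, at 2.03. Indirect pathway genes had 6 of 7 adjusted over the list alone and 0 over all genes (median 1.34), with Gpr6 at 2.05 and Ptprm at 0.51. Their camera adjusted p were 3.59e-04 and 1.58e-05, and both had an adjusted p of 0.279 with an estimated correlation. Drd1, Pdyn, Tac1, Drd2, Penk and Adora2a sit in more than one of these lists. Dopamine, opioid and cannabinoid signalling genes share several members too, with 12 rises and 4 falls of 25 adjusted over the list alone, 0 over all genes and a median of 0.52. The dopamine receptor Drd3 was at 1.54 and the striatal G-protein regulator Rgs9 at 2.45. The camera adjusted p was 0.00156, and the adjusted p was 0.449 with an estimated correlation. The medium spiny list was instead lower under the accession labels (median -0.42, camera adjusted p = 2.38e-04, adjusted p = 0.881 with an estimated correlation).

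Markers of cortical excitatory neurons fell as a group, with 13 of 15 falling adjusted over the list alone, 0 over all genes and a median of -1.19. Emx1, a cortical transcription factor, was at -0.64 (SE 0.09) and Cux2, of upper cortical layers, at -1.06 (SE 0.21), beside Bdnf. The camera adjusted p was 4.37e-09, and the adjusted p was 0.279 with an estimated correlation. Grouped by accession, the list was higher (median 0.47, camera adjusted p = 4.79e-05, adjusted p = 0.881 with an estimated correlation). The striatal list mean also differed within a group, at -1.13, -0.71 and -0.17 in LV-GFP rats 1, 3 and 9, where the cortical list mean was 0.77, 0.53 and 0.40 (log2 deviation from the mean of all 6 rats). The values for rats 6, 8 and 10 were 0.62, 0.55 and 0.85 for the striatal and -0.36, -0.25 and -1.08 for the cortical list.

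Immediate early genes, which respond to neuronal activity, fell for 11 of 23 members adjusted over the list alone and 0 over all genes (median -0.40). Egr1 was at -0.82 (SE 0.12), Egr2 at -0.90 and Fos at -0.58, beside Arc. The camera adjusted p was 5.53e-07, and the adjusted p was 0.279 with an estimated correlation. Glutamate synapse and plasticity genes had 15 falls and 2 rises of 36 adjusted over the list alone, 0 over all genes and a median of -0.30. Syn1, a synaptic vesicle protein, was at -0.90 and the kinase Camk2d at -0.67, and the list includes Bdnf, Arc and Camk2a. The camera adjusted p was 3.64e-06, and the adjusted p was 0.449 with an estimated correlation. Cortical markers moved the same way in the same rats. Under the accession labels both medians were positive, 0.10 and 0.12.

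Interferon response genes rose for 22 of 24 members adjusted over the list alone and 0 over all genes, with a median of 1.31. The antiviral genes Mx1, Rsad2 and Oas1b were at 2.68 (SE 0.57), 1.95 (SE 0.45) and 1.44 (SE 0.29). The list mean was 1.06 in rat 6, -0.22 in rat 8 and 1.61 in rat 10, against -0.57, -1.0 and -0.87 in LV-GFP rats 1, 3 and 9. The camera adjusted p was 1.36e-11, and the adjusted p was 0.449 with an estimated correlation. Its median was -0.26 with the accession labels.

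Microglia and macrophage genes rose for 12 of 24 members adjusted over the list alone and 0 over all genes (median 1.36). Itgam, a microglial integrin, was at 1.68, the chemokine Ccl2 at 2.22 and the complement gene C1qa at 1.47. Lymphocyte and antigen presentation genes rose for 11 of 16 adjusted over the list alone and 0 over all genes (median 1.43), with the class II gene RT1-Ba at 2.18 and the immunoproteasome subunit Psmb8 at 1.91. Their camera adjusted p were 6.12e-08 and 3.61e-06, with an adjusted p of 0.449 for each with an estimated correlation. Rat 8 had a microglia list mean of -0.37, within the LV-GFP range of -0.80 to -0.30, while rats 6 and 10 were at 0.95 and 1.13. For lymphocyte genes rat 8 was at -0.18, just above LV-GFP rat 1 at -0.22, while rats 6 and 10 were at 0.71 and 1.51. Reactive astrocyte genes had list means of 0.75, -0.38 and 0.95 in rats 6, 8 and 10, with rat 8 inside the LV-GFP range of -0.69 to 0.04. Their median log2 fold change was 0.72, with 0 of 16 past adjusted over the list alone or over all genes, a camera adjusted p of 0.00156 and an adjusted p of 0.566 with an estimated correlation. The medians of these 3 lists under the accession labels were -0.04, -0.14 and 0.07.

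**Figure D3:**
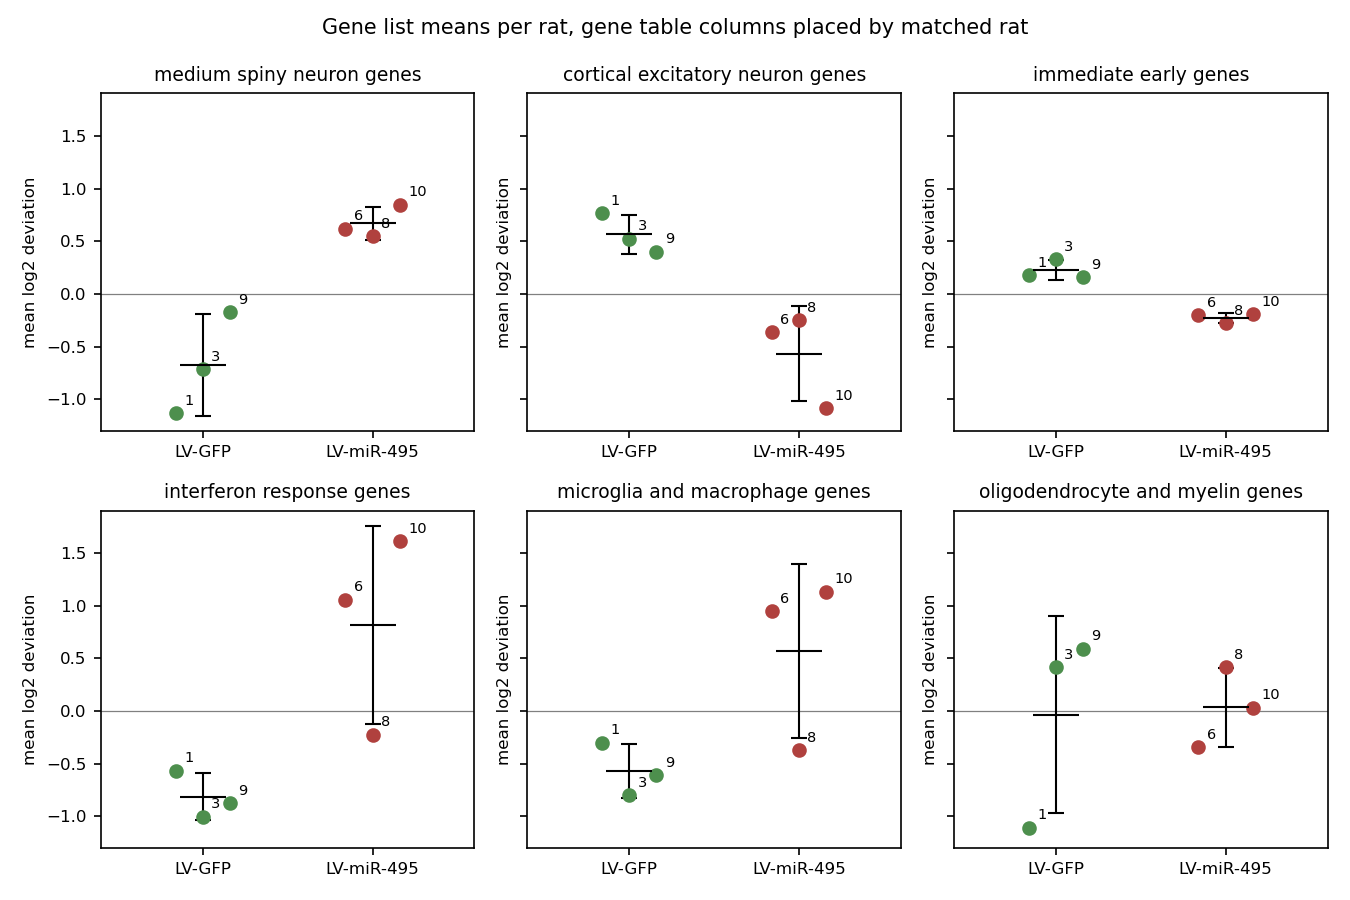
Mean log2 deviation (vertical axis, from each gene's mean over 6 rats) of 6 gene lists in each rat, with gene table columns placed by matched rat. Points are rats with their numbers, and bars are the group mean ± SD (n = 3). Medium spiny neuron genes lie above 0 in the LV-miR-495 rats and cortical genes below 0, while rat 8 lies at -0.22 for interferon genes.

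In all, 12 of the 24 lists passed camera with the preset correlation, 8 higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.279. With fry, which does not compare a list with other genes, 7 passed: reported targets, medium spiny, direct and indirect pathway, cortical, immediate early and microRNA machinery genes (adjusted p = 0.0179 to 0.0269). Past camera but not fry were interferon and glutamate synapse genes (fry adjusted p = 0.111 each), microglia and lymphocyte genes (0.172 each), reactive astrocyte genes (0.302) and dopamine, opioid and cannabinoid genes (0.0818). The lists that passed neither form of camera were striatal interneuron, septum and ventral pallidum, choroid plexus, astrocyte, myelin, oligodendrocyte precursor, endothelial, blood, microRNA machinery, cell death, oxidative phosphorylation and miR-495 cluster genes. Interneuron genes went both ways adjusted over the list alone, 3 rises and 4 falls of 14, with the choline transporter Slc5a7 at 1.61 and Vip at -1.45. Adjusted over the list alone, the septum and pallidum list had 2 rises and 2 falls of 13, the former Dlk1 and Nts (1.86). Members of the miR-495 cluster had 1 rise of 14 adjusted over the list alone, Dlk1, a protein-coding gene. The list median was 0.13 (camera adjusted p = 0.224), and it was 0.37 without rat 3 (camera adjusted p = 5.97e-04, 0.487 with an estimated correlation) and 0.14 with dim genes kept (camera adjusted p = 0.0263, 0.651 estimated). The myelin list had a median of 0.08 (camera adjusted p = 0.802), but without rat 1 its median was -0.41 (camera adjusted p = 4.58e-05, 0.495 with an estimated correlation). With the accession labels 5 lists passed at the preset correlation, and 10 with the replicate number as a block, against 0 for each with an estimated one. Among the 5 were myelin (median -0.52, camera adjusted p = 2.91e-09, 0.881 estimated) and the miR-495 cluster (median -0.44, camera adjusted p = 1.30e-09, 0.561 estimated).

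The authors' deposited table lists 1027 transcript clusters, all with a ratio under 0.75 (0.197 to 0.7497). Its means equal those of rats 1 and 3 against rats 6 and 10, so rats 8 and 9 did not enter it. In the fit of all 6 rats, the 1027 clusters were all lower in the LV-miR-495 mean. Of the 984 tested, 780 had an unadjusted limma p under 0.05 and 7 passed the adjusted threshold. Rats 1, 3, 6 and 10, over which the clusters were chosen, are also in this fit. The direction and the small p were thus largely fixed by that choice. In rats 8 and 9, which were not used to choose the clusters, 833 (81.1%) were lower in rat 8 than in rat 9, with a median log2 difference of -0.19 against -0.59 in the authors' arrays. In 10000 random lists matched on expression, the median lay between -0.03 and 0.02. Random lists were not drawn to vary together as a chosen list can, so that range may be too narrow. Rising clusters behaved likewise: of 2405 with a ratio over 4/3 in the authors' arrays, 73.2% were higher in rat 8 than in rat 9. Both results compare a single pair of rats, which also differed in the neuron lists in the direction of the groups. The medium spiny list mean was 0.55 in rat 8 and -0.17 in rat 9, and the cortical one -0.25 and 0.40. The ratio of rat 8 to rat 9 was 0.641 for Arc, 0.716 for Bdnf and 1.002 for Camk2a.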

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

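Leaving out rats 8 and 9 together, regrouping the gene table, the block on columns placed by rat and an estimated correlation combined with another change were chosen after the data were examined, and the cause of each change below was not tested unless given. Cluster counts (45 higher, 20 lower) moved as follows: 40 lower with quantile normalization, 27 higher with no filter, 2994 and 3441 with array weights, 266 and 282 at an adjusted p under 0.1, 520 and 242 without rats 8 and 9. The array weights did not converge and gave rat 6 a weight of 9.71. Leaving out single rats gave 0 to 1286 higher and 0 to 876 lower, with 0 in both directions without rat 1, 3, 6 or 10, 34 and 12 without rat 9, and the maximum without rat 8. The gene table in place of the clusters gave 13 higher and 2 lower by matched rat and 0 and 0 by accession labels. All 65 called clusters kept their sign in every setting of the cluster table where they were tested, the block on columns placed by rat included. Their groups do not overlap, so leaving out rats, or the block that compares rats 8 and 9, could not turn a sign. For those settings the kept signs were fixed beforehand and are no check. Of the 65, 65 were called with quantile normalization, 63 without rats 8 and 9 and 30 without rat 9.

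Gene table counts (13 rose, 2 fell) became 51 and 19 with quantile normalization, 0 and 0 with no filter, 37 and 14 with the lowest 50% left out, 43 and 17 with a trended robust prior, 1996 and 1847 with array weights, 264 and 240 at an adjusted p under 0.1, and 433 and 194 without rats 8 and 9. Leaving out single rats gave 0 to 1067 and 0 to 709, with 0 in both directions without rat 1, 3, 6 or 10 and the maximum without rat 8. Without rat 9, 34 rose. The count of lists past the threshold (12) was 11 to 14 in the other settings, 12 to 14 with single rats left out, 0 with an estimated correlation and 5 by accession labels. The share of the authors' clusters lower in rat 8 stayed between 79.8% and 81.8%.

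Among lists and genes past the threshold, signs reversed only under the accession labels. That regrouping moves 4 of the 6 columns to the opposite group, so these reversals were largely fixed by it. Lists short of the threshold, such as myelin without rat 1, changed the sign of their medians in other settings too. Under the accession labels, list medians became 0.18 for reported targets, -0.42 for medium spiny, -0.27 for direct and -0.55 for indirect pathway, 0.47 for cortical, -0.14 for lymphocyte, -0.26 for interferon, 0.10 for immediate early, 0.12 for glutamate synapse and -0.30 for dopamine and opioid genes. Log2 fold changes became -0.53 for Gpr149, -0.38 for Htr4, -0.40 for Foxp2, -0.44 for Rxrg, -0.49 for Dlk1, -0.38 for Pde10a, -0.40 for Sh3rf2, -0.36 for Foxo1, -0.27 for Adamts6, -0.26 for Kctd8, -0.33 for Gpr101, 0.63 for Tshz3 and 0.54 for Tmem178a.

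Under the accession labels the fit with the replicate number as a block passed 0 genes, as did the unblocked one, and 10 lists against 5 (0 for each with an estimated correlation). When the matched rats took over these numbers, the block left 0 clusters and 0 genes past the threshold in both directions, and 13 lists (0 with an estimated correlation). Only 1 number then holds both groups (rats 8 and 9), so that fit compares a single pair of rats with 2 residual degrees of freedom. At an unadjusted p under 0.05 it gave 490 higher and 559 lower clusters and 313 and 227 genes. Not run were the seed site tests, the choice of the highest probe set per gene (the gene table has 1 row per gene) and the cluster table for lists and most named genes, since its rows are unnamed. Dim features such as Mir495 limit what a small change can show.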

Other observations

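All tests of explanations in this part, the splits of the rats included, were written down after the results they bear on were seen. Among genes outside the descriptions above, microRNA machinery genes differed little, with a median log2 fold change of 0.06 over 14 genes and 0 past the threshold over the list alone, and fry's adjusted p was 0.0179 against 0.239 for camera. Oxidative phosphorylation genes had a median of 0.05 over 25 and astrocyte genes 0.03 over 15, both with 0 past over the list alone. Drd2, a gene singled out after its values were seen, differed by 3.70 on the log2 scale between LV-GFP rats 9 and 1. The median difference between these rats over the 29 medium spiny neuron genes was 0.69.

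The columns of the gene table match arrays of rats in the opposite group. The mean r of the best assignment of columns to rats was 0.955, against 0.773 for the next best. An assignment that keeps every column in its labelled group reached 0.176 at most, which argues against a mere difference in processing between correctly placed columns. For 4 columns the same array thus stands under opposite groups in the 2 tables, so at least one table has columns under the wrong sample. The rise of Mir495 by 0.61 (unpooled SE 0.30) in rats 6, 8 and 10 does not settle which labels are wrong. Its probe set was dim, and 3 against 3 cannot pass an exact test. The design text and the authors' deposited table use the rat names.

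Striatal neuron genes were higher and cortical neuron genes lower in LV-miR-495 rats. A candidate explanation is that the dissections held different shares of striatum and cortex. Rats given the same virus then also differ in opposite directions in both lists, and this held in 6 of 6 within-group pairs (exact one-sided permutation p = 0.0278). The lists were tested without Bdnf and Camk2a, and the cortex minus striatum score had a range of 1.34 within LV-GFP rats against a group difference of -2.57. With that score as a covariate, the mean of Bdnf, Arc and Camk2a differed by -0.33 (SE 0.23) between groups, against -0.63 (SE 0.10) without it. The interval of -1.04 to 0.39 includes both 0 and the unadjusted value, so lowering by miR-495 and by tissue share cannot be told apart for these 3 genes, and an effect of miR-495 on either list stays open and untested. The score was not fitted to the genes past the threshold. Among LV-GFP rats, rat 9 had the lowest score, 0.62. There the named rising genes past the threshold were highest, and Tshz3 and Tmem178a lowest. For these genes too, tissue share and miR-495 were not told apart.

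Interferon, microglia and lymphocyte genes were higher in LV-miR-495 rats. A response of one size in all 3 rats would put rat 8 near rats 6 and 10, but for interferon genes rat 8 lay 27.5% of the way from the LV-GFP mean to their mean, 12.1% for microglia and 27.7% for lymphocyte genes. A single rat does not exclude it. Blood left in the tissue would raise haemoglobin about as much as these lists, whose smallest median was 1.31. Haemoglobin genes differed by 0.0756 (SE 0.42), which with 2 SE reaches 0.92 and argues against blood as the source of a rise of that size. That bound was set after the values were seen, in place of a first bound of 0.5 that left blood undecided. A Welch interval, which reaches 1.63, would leave it undecided under either bound. The pooled interval reaches 1.25, and the limma intervals of Hbb and Hba-a1 reach 0.97 and 0.65. Hbb was at 10.72, 10.62 and 9.45 in rats 6, 8 and 10, against 10.43, 10 and 9.89 in rats 1, 3 and 9. The small difference thus depends on rat 10, which had the lowest Hbb. The titre of LV-miR-495 was 1.68 times that of LV-GFP, and titre and group cannot be told apart because each group had a single titre. A response to miR-495 itself is confounded with titre in the same way and stays open.

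Splitting the 6 rats 3 against 3 gives 10 splits, too few for a share under 0.05. The real split here is the one by rat name, although which labels are wrong was not settled. It gave 65 clusters past the threshold and the highest other split 1, so 1 of 10 splits reached the real value. The split by accession labels (rats 1, 6 and 9 against 3, 8 and 10) is counted among the other splits. That split gave 0 clusters, 0 genes and 5 lists past the threshold. The comparison takes the rat names as given, so it cannot decide between the labels. At an unadjusted limma p under 0.05 the real split gave 4589 clusters and the other splits 146 to 2763. The highest of these was rats 1, 6 and 10 against 3, 8 and 9. For the gene table by matched rat the real split gave 15 genes and the highest other split 1, again 1 of 10. For gene lists the real split gave 12 and the highest other split 10, and 1 of 10 reached the real value.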
